A study of Homo sapiens with 12 samples.

How the data were processed

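Poly(A) RNA sequencing counts of DLD1 cells were analysed in 4 groups of 3 libraries, 12 in all: DMSO, TCDD, kynurenine and CH223191, the compounds at 10 µM each, all after 1 h. Per the labels, the authors trimmed reads with Trim Galore, aligned them to the human genome hg38 with STAR 2.7.2b, sorted them with SAMtools 1.9 and counted reads per gene with HTSeq, so the deposited values are raw read counts per gene symbol. The protocol text differs in part: it names NGS QC Toolkit 2.3.3 for read quality, Bowtie 2.3.2 with Ensembl release 89 transcripts for library quality and STAR 2.5.2b for alignment, and it does not mention CH223191. The strand setting of the counting is not stated, so genes that overlap on opposite strands, such as CYP1B1, CYP1B1-AS1 and RMDN2, may share reads. Every file held whole numbers for the same 26485 symbols and the HTSeq summary counters.

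Each library was named by its label, and 0 were left out. Pairs of libraries within a group were checked for duplicates by the variance of their counts relative to Poisson noise, which was 1.76 to 4.65 in 12 pairs of the same group and 2.00 to 21.5 in 54 other pairs. Replicate numbers were checked as possible pairs by correlating each library's deviations from its group mean, which gave -0.055 to 0.037 in 18 pairs with the same number and -0.053 to 0.083 in 36 others, so no pairing was used.

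Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with too few reads were left out by filterByExpr (minimum count 10), which kept 13619, and libraries were scaled by their totals and TMM factors (0.988 to 1.02). A quasi-likelihood model with 1 coefficient per group and no block was fitted to all 12 libraries, each pair of groups was compared by the quasi-likelihood F test, and a joint F test covered the 4 groups. P-values were adjusted by Benjamini-Hochberg within each comparison, with an adjusted p under 0.05 taken as a call, and each p beside a gene or a count comes from this test with 3 libraries per group. CPM values used the scaled totals, log2 CPM a prior count of 2, and principal components the log2 CPM of the tested genes.

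Of 29 hand-written gene lists, 28 were tested by camera with a preset inter-gene correlation of 0.01 and at least 5 measured members, with Benjamini-Hochberg adjustment over the lists. The list of mitochondrially encoded genes had 0 members in the files. Camera with a correlation estimated per list and the rotation test fry were run beside it, and member calls were given over all genes and adjusted over the list alone. Estimating the correlation changed more than the correlation used. With TCDD the AHR target list had an estimated value of -0.0010, below the preset, yet its adjusted camera p rose from 5.1e-26 to 6.5e-05. A call lost in this setting is therefore not shown to be lost through correlation between genes.

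The lists, the comparisons, the alternatives and the naming rule were fixed before the data were examined. The rule names the 12 largest rises and 12 largest falls against DMSO and the 6 largest each way between compounds, among called genes with a mean of at least 1 CPM over the 12 libraries and no overlap between libraries, leaving out symbols that start with MIR, SNOR, SCARNA, RNU or RNA5. It adds CYP1A1, CYP1A2, CYP1B1, AHRR, TIPARP, NQO1, SLC7A5, AHR, ARNT and MYC, and up to 4 members of smallest p from each list described.

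The alternatives were RLE factors, library totals alone, no low-count filter, at least 5 CPM in 3 libraries, a replicate block, DESeq2 1.42.0, only the 2 groups compared, and each library left out in turn. Removal of GC content and transcript length trends, with gene models of GENCODE 44 (23161 symbols matched), was added after the data were seen. Agreement between compounds was compared with 100 simulations of unchanged genes with shared controls.

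The procedure was tested on simulated data. Of 50 planted genes each at absolute log2 changes of 0.2, 0.4, 0.8 and 1.6, it called 52, 70, 98 and 100%, and it called 4 of 13203 unchanged genes. In a comparison with nothing planted it called 0 of 13403 by edgeR, and with 1 list planted it called that list and 1 of 27 others. The simulated genes were drawn independently, whereas the estimated correlation of the real ribosomal protein list was 0.77. The false calls of the list tests in the real data were thus not measured. Library depth was 21397703 to 28247146 counted reads.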

Results

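RNA of DLD1 cells, an established human colon adenocarcinoma line, was sequenced after 1 h with DMSO, the vehicle, or with 10 µM of 1 of 3 chemicals that act on the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. TCDD, a dioxin, is its prototypical strong agonist, kynurenine is a tryptophan metabolite described as an endogenous agonist, and CH223191 is a synthetic antagonist. Each of the 4 groups had 3 libraries, 12 in all. Reads counted on named genes ranged from 21397703 to 28247146 per library (median 26666641), and 16675 to 17099 genes had at least 1 count. The share of reads in no annotated gene was 7.94 ± 0.666% in DMSO, 7.33 ± 0.282% with TCDD, 7.06 ± 0.238% with kynurenine and 6.97 ± 0.357% with CH223191, and the share aligned to more than 1 place was 3.51 ± 0.348% with TCDD against 2.90 ± 0.236% in DMSO. Of 26485 gene symbols counted, 13619 had enough reads to be tested, and the common biological coefficient of variation was 3.22%. The labels do not say whether the 3 libraries of a group came from separate cultures, so each p-value rests on the spread between these libraries.

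The TCDD and the CH223191 libraries separated from the rest, and those of DMSO and kynurenine lay close to each other. On the first principal component, with 32.6% of the variance, the CH223191 libraries lay at 23.4 to 23.7 and TCDD libraries at -13.3 to -13.1. The DMSO libraries lay at -4.87 to -4.32 there and the kynurenine libraries at -6.44 to -5.20, close together but without overlap. On the second, with 12.5%, the TCDD libraries lay at -14.9 to -9.26. The DMSO and kynurenine libraries lay above them at 4.49 to 10.6 and overlapped each other. Across the 4 groups, 5932 of 13619 genes differed at an adjusted p under 0.05.

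TCDD was compared with DMSO to measure the early response to strong AHR activation. CYP1A1, the xenobiotic-metabolising monooxygenase that is the classical AHR target, rose 133-fold, from 3.22 ± 0.142 to 428 ± 15.9 CPM (reads scaled to library depth; SD, n = 3; log2 fold change 7.05 ± 0.0634 SE, adjusted p = 5.5e-42). CYP1B1, a related monooxygenase, rose 5.13-fold from 126 ± 1.56 to 646 ± 5.84 CPM, and AHRR, the repressor that competes with AHR, rose 3.73-fold from 6.25 ± 0.354 to 23.4 ± 1.49 CPM. TIPARP, an ADP-ribosyltransferase that lowers AHR activity, rose 3.30-fold to 145 ± 5.69 CPM, and ALDH1A3, a retinaldehyde dehydrogenase, rose 3.30-fold from 9.34 ± 0.437 to 30.8 ± 1.09 CPM. On hg38, CYP1A1 lies on chromosome 15 at 74719542 to 74725536, CYP1B1 on chromosome 2 at 38066973 to 38109902, AHRR on chromosome 5 at 321714 to 438291 and TIPARP on chromosome 3 at 156673235 to 156706770. CYP1A2, whose sequence is close to that of CYP1A1, had a log2 fold change of 2.61 ± 0.298 SE at 2.44 CPM against 0.392 CPM in DMSO, and reads of the 2 paralogs may not have been fully separated.

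Further large rises with TCDD were in ADGRF1, an adhesion receptor (log2 fold change 2.44), ITPR1, the calcium release channel of the endoplasmic reticulum (1.81), BMF, a pro-apoptotic member of the BCL2 family (1.65), and ABCG2, a drug efflux transporter (1.35). RN7SK (1.28) and RMRP (1.16), both non-coding RNAs without a poly(A) tail, rose too, and both calls held with each library left out. Poly(A) libraries capture such RNAs poorly, and whether capture differed between the groups was not tested. Between TCDD and kynurenine the RMRP call (adjusted p = 0.042) ended in 4 of 12 fits with a library left out (highest 0.37). Among genes with a mean of at least 1 CPM and no overlap between the groups, the limits used here to name large changes, falls were smaller than rises. NR4A3, an immediate-early nuclear receptor (-0.69), OSR1, a zinc finger transcription factor (-0.67), SOCS2, a feedback inhibitor of cytokine signalling (-0.59), CXCL1, a neutrophil chemokine (-0.54), and CPA4, a carboxypeptidase (-0.53), fell. FGF20 (-0.99), NPAS1 (-0.77), SP8 (-0.76), FAM81A (-0.71), ADORA1 (-0.62), AUTS2 (-0.54) and RNF122 (-0.53) passed with 12 libraries but not with each library left out. NQO1, a quinone reductase (0.17), and SLC7A5, a transporter of large neutral amino acids (0.16), rose slightly, and the oncogene MYC fell (-0.20). For AHR itself the log2 fold change was -0.10 (adjusted p = 0.11), with -0.15 and a call without TCDD replicate 3 and -0.17 and a call once GC and length trends were removed, and for its partner ARNT it was -0.01 (adjusted p = 0.90).

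Of the list of AHR target genes, 13 of 20 measured members rose and 1 fell (13 and 2 adjusted over the list alone), with a median log2 fold change of 0.34 (camera adjusted p = 5.1e-26, and 6.5e-05 with an estimated correlation). The member that fell was CYP2S1 (-0.23), named after its values were seen. This was the only list of 28 tested whose call with TCDD held with an estimated correlation. In the list of AHR complex and regulators, 5 of 16 rose and 1 fell, among them the coactivators NCOA3 (0.25) and EP300 (0.24), with AHRR and TIPARP shared with the target list (adjusted p = 0.0018, and 0.20 with an estimated correlation). In the list of NF-kB and inflammatory genes 4 of 25 rose and 10 fell (4 and 10 adjusted over the list alone). The chemokines CXCL1 (-0.54) and CXCL3 (-0.44) fell, and the apoptosis inhibitor BIRC3 (0.44) and the cytokine LIF (0.38) rose (adjusted p = 0.018, and 0.28 with an estimated correlation).

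Growth-related lists moved little per gene with TCDD. Ribosome biogenesis genes had 0 of 30 higher and 9 lower (1 and 11 adjusted over the list alone), such as MYBBP1A (-0.25) and BOP1 (-0.22) (adjusted p = 0.0014, and 0.12 with an estimated correlation). Of the cytoplasmic ribosomal proteins 16 of 82 fell and 0 rose (20 and 0 adjusted over the list alone), with RPLP2 at -0.21 and RPL28 at -0.17 (adjusted p = 1.6e-08, and 0.71 with an estimated correlation). Of the G1/S and replication genes 7 of 25 fell and 0 rose (10 and 0 adjusted over the list alone), among them the replication licensing factors CDT1 (-0.25) and MCM5 (-0.16) (adjusted p = 4.5e-04, and 0.20 with an estimated correlation). Of the MYC target genes 4 of 24 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.017, and 0.48 with an estimated correlation), and of the nucleotide synthesis genes 3 of 20 fell and 0 rose (3 and 0 adjusted over the list alone; adjusted p = 0.031, and 0.48 with an estimated correlation). Of the G2/M genes 6 of 25 rose and 1 fell (7 and 2 adjusted over the list alone), with MKI67 at 0.26 and CENPF at 0.24 (adjusted p = 0.029, and 0.48 with an estimated correlation). Of the heat shock genes 7 of 23 rose and 1 fell (9 and 1 adjusted over the list alone), with the chaperones HSPA5 at 0.16 and HSPH1 at 0.14 (adjusted p = 0.0079, and 0.48 with an estimated correlation).

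Some transcripts that lack a poly(A) tail or stay in the nucleus rose with TCDD. Of 33 replication-dependent histone genes 4 rose and 0 fell (4 and 0 adjusted over the list alone), with HIST2H2BF at 1.11 and a list median of 0.37 (adjusted p = 4.1e-04, and 0.20 with an estimated correlation). HIST2H2BF kept its call with each library left out. The call ended for HIST1H3B without DMSO replicate 2 or 3 or TCDD replicate 2 or 3 (highest adjusted p = 0.12), for HIST1H4E without DMSO replicate 1 or 2 or any TCDD library (0.19), and for HIST1H2BE without DMSO replicate 1 or 3, TCDD replicate 1 or 2, kynurenine replicate 3 or CH223191 replicate 2 (0.23). MALAT1, a nuclear non-coding RNA, rose (0.47), but the list of nuclear-retained and snoRNA host RNAs was not called, with 4 of 20 higher and 0 lower (4 and 1 adjusted over the list alone; adjusted p = 0.13, and 0.76 with an estimated correlation). Its median was -0.0018 while its mean was 0.16 and the camera direction was up. Of 385 ZNF zinc finger genes 23 rose and 5 fell (17 and 1 adjusted over the list alone; adjusted p = 0.046, and 0.48 with an estimated correlation). Of the markers of other cell types, 0 of 8 fibroblast, 0 of 9 immune and 0 of 8 endothelial genes passed with TCDD by edgeR, over all genes or over the list alone, with 0, 0 and 0 at an unadjusted p under 0.05 and 0, 0 and 0 called by DESeq2.

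In total TCDD changed 1599 of 13619 genes, 805 higher and 794 lower, with 3377 genes at an unadjusted p under 0.05. Of these 86 were at least 1.5-fold higher and 12 at least 1.5-fold lower. Each gene named as a large rise or fall with TCDD, kynurenine or CH223191 had 3 libraries that did not overlap the 3 DMSO libraries, as the naming rule required. Chance gives this for 10% of genes, and for genes chosen by it the lack of overlap is no separate evidence. The count was 805 without TCDD replicate 3, 851 without DMSO replicate 1, 1020 without DMSO replicate 3 and 1055 with GC content and transcript length trends removed, a setting chosen after seeing the data. In this order 790, 818, 979 and 803 of these were among the 1599. Of the 818 shared without DMSO replicate 1, 1 had the opposite sign. It was the ribosomal RNA gene RNA18S5, chosen after its values were seen, at -2.84 (adjusted p = 0.024) with 12 libraries and 3.02 (0.049) without that library, which held 98.9 CPM of it. Its call ended without TCDD replicate 1 or 3 (highest adjusted p = 0.12). The call ended for FGF20 without TCDD replicate 1 or 3 (highest adjusted p = 0.10), for AUTS2 without DMSO replicate 2 or TCDD replicate 3 (0.070), for ADORA1 without DMSO replicate 1 or TCDD replicate 2 (0.13), for RNF122 without DMSO replicate 2 or 3 or TCDD replicate 1 or 2 (0.14), for FAM81A without DMSO replicate 2 or 3 or TCDD replicate 1 or 3 (0.10), for NPAS1 without DMSO replicate 1 or 3 or any TCDD library (0.16) and for SP8 without any DMSO library, TCDD replicate 1 or 3, kynurenine replicate 2 or 3 or CH223191 replicate 2 or 3 (0.21). With 1 library left out, list calls ended for G2/M genes (highest adjusted p = 0.086, TCDD replicate 3; also DMSO replicate 1), heat shock genes (0.057, DMSO replicate 2), MYC targets (0.054, TCDD replicate 2), nucleotide synthesis (0.16, TCDD replicate 2; also DMSO replicate 2) and ZNF genes (0.36, DMSO replicate 3; also TCDD replicates 2 and 3 and kynurenine replicate 1).

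**Figure D1:**
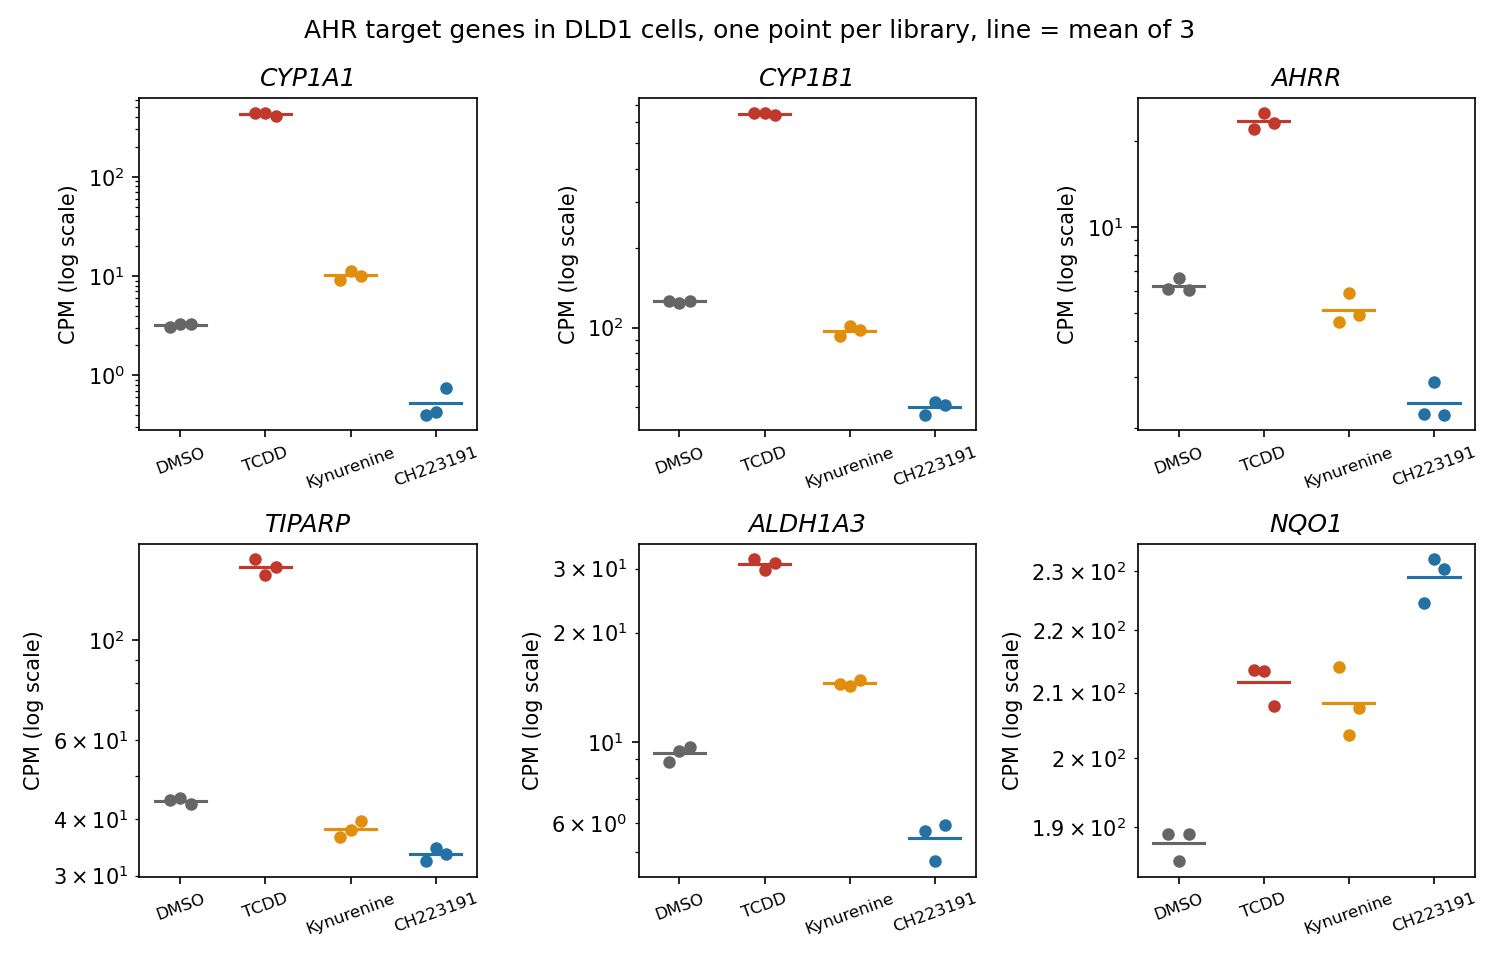
Expression in CPM (logarithmic axis) of CYP1A1, CYP1B1, AHRR, TIPARP, ALDH1A3 and NQO1 in each of the 12 libraries, with 1 point per library and a line at each group mean. CYP1A1 ran from 0.520 CPM with CH223191 through 3.22 CPM in DMSO and 10.1 CPM with kynurenine to 428 CPM with TCDD, whereas CYP1B1, at 126 CPM in DMSO, lay at 97.5 CPM with kynurenine and 646 CPM with TCDD.

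Kynurenine was compared with DMSO to measure the early response to the endogenous ligand. CYP1A1 rose 3.15-fold, from 3.22 ± 0.142 to 10.1 ± 1.01 CPM (SD, n = 3; log2 fold change 1.65 ± 0.101 SE, adjusted p = 9.0e-14). ITPR1 (log2 fold change 0.96), ABCG2 (0.85), ADGRF1 (0.85) and ALDH1A3 (0.63), which TCDD also raised, were next among genes with a mean of at least 1 CPM, followed by SCIN, an actin-severing protein (0.61), ALPP, placental alkaline phosphatase (0.45), RARRES2, the chemerin precursor (0.38), ALDH3A1, an aldehyde dehydrogenase (0.34), OSBP2, an oxysterol-binding protein (0.30), and GDA, guanine deaminase (0.29). ALPP has close paralogs whose reads may not have been fully separated. Below that limit STMND1, chosen after its values were seen, had a larger log2 fold change (2.69, adjusted p = 0.022), from 0.0735 ± 0.0360 to 0.496 ± 0.221 CPM, and its call ended without any DMSO library or kynurenine replicate 1 (highest 0.22). In the opposite direction, CYP1B1 fell from 126 ± 1.56 to 97.5 ± 4.26 CPM (log2 fold change -0.37 ± 0.0388 SE, adjusted p = 2.4e-07).

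Other genes that kynurenine lowered included PIM1, a serine/threonine kinase (-0.32), SEMA5A, an axon guidance semaphorin (-0.30), NEDD9, an adhesion scaffold protein (-0.28), SLC2A1, the main glucose transporter (-0.28), EREG, a ligand of the EGF receptor (-0.23), and CEMIP, a hyaluronan-degrading protein (-0.22). MEGF6 (0.38), MB21D2 (-0.36), ACSS1 (-0.32), DAB2 (-0.26), FAM189A1 (-0.24), TIPARP (-0.21) and NQO1 (0.15) passed with 12 libraries but not with each library left out. CYP1A2 had a log2 fold change of 1.34 at 1.01 ± 0.0707 CPM that did not pass (adjusted p = 0.11), though it passed with no low-count filter (0.0069) and without CH223191 replicate 3 (0.037). AHRR (-0.28, adjusted p = 0.55), SLC7A5 (0.08, 0.63), AHR (-0.01, 0.99), ARNT (0.02, 0.98) and MYC (0.12, 0.31) did not pass.

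Of the AHR target list 4 of 20 members rose and 4 fell with kynurenine (7 and 5 adjusted over the list alone). CYP1A1, ALDH1A3, ALDH3A1 and NQO1 were higher, and CYP1B1, NEDD9, EREG and TIPARP were lower. The list median was -0.04 while the mean was 0.13 and the camera direction was up (adjusted p = 0.46). Of the heat shock genes 1 of 23 rose over all genes, and 8 rose adjusted over the list alone. The inducible chaperone HSPA1B rose (0.25), and its reads may be shared with the nearly identical HSPA1A (adjusted p = 1.2e-12 for the list, and 0.21 with an estimated correlation). Of the NRF2 targets, genes of the oxidative stress response, 1 of 22 rose and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 1.9e-04, and 0.21 with an estimated correlation). For the ribosomal proteins, with 0 of 82 past the gene test by edgeR, the list value was 3.1e-04, and 0.80 with an estimated correlation. Without DMSO replicate 2 it was 0.38, and without that library or kynurenine replicate 1 (0.038) the direction turned. For cholesterol synthesis genes, with 0 of 27 past the gene test (4 higher and 2 lower adjusted over the list alone), it was 0.033, and 0.68 with an estimated correlation. It ended without DMSO replicate 1 or 2 or kynurenine replicate 2 or 3 (highest 0.69). Of the 28 lists, 0 kept a call with kynurenine under an estimated correlation.

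In total kynurenine changed 40 genes, 21 higher and 19 lower, with 7 at least 1.5-fold higher, 0 at least 1.5-fold lower and 913 genes at an unadjusted p under 0.05. TCDD also changed 36 of the 40. The other 4 included SLC2A1, CYR61, a matrix protein (-0.17), and ID1, an inhibitor of helix-loop-helix factors (0.18). The call ended for ID1 without DMSO replicate 1 (adjusted p = 0.076) or kynurenine replicate 3, and for CYR61 without any DMSO library, TCDD replicate 1 or kynurenine replicate 2 or 3 (highest 0.22). Kynurenine replicate 1 stood apart from its group. The variance of counts relative to Poisson noise was 4.65 and 4.60 against replicates 2 and 3, and 1.76 between these. Without it 42 genes were called, 30 higher and 12 lower, 29 of them shared with the 40, and 9 lists in place of 4. The count was 65 with no low-count filter and 26 when fitted on the 6 libraries compared. The call ended for MEGF6 without DMSO replicate 2 or kynurenine replicate 2 or 3 (highest adjusted p = 0.14), ACSS1 without DMSO replicate 1 or 3 or kynurenine replicate 2 or 3 (0.14), DAB2 without DMSO replicate 2 or kynurenine replicate 3 (0.096), FAM189A1 without DMSO replicate 1 or 3 or kynurenine replicate 1 (0.14), TIPARP without any DMSO library or kynurenine replicate 1 or 2 (0.15), NQO1 without any DMSO library or kynurenine replicate 1 or 3 (0.15), and MB21D2 without TCDD replicate 1 or any of the 6 libraries compared (0.17). MB21D2 (0.081), ACSS1 (0.072) and FAM189A1 (0.055) did not pass with DESeq2 either.

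**Figure D2:**
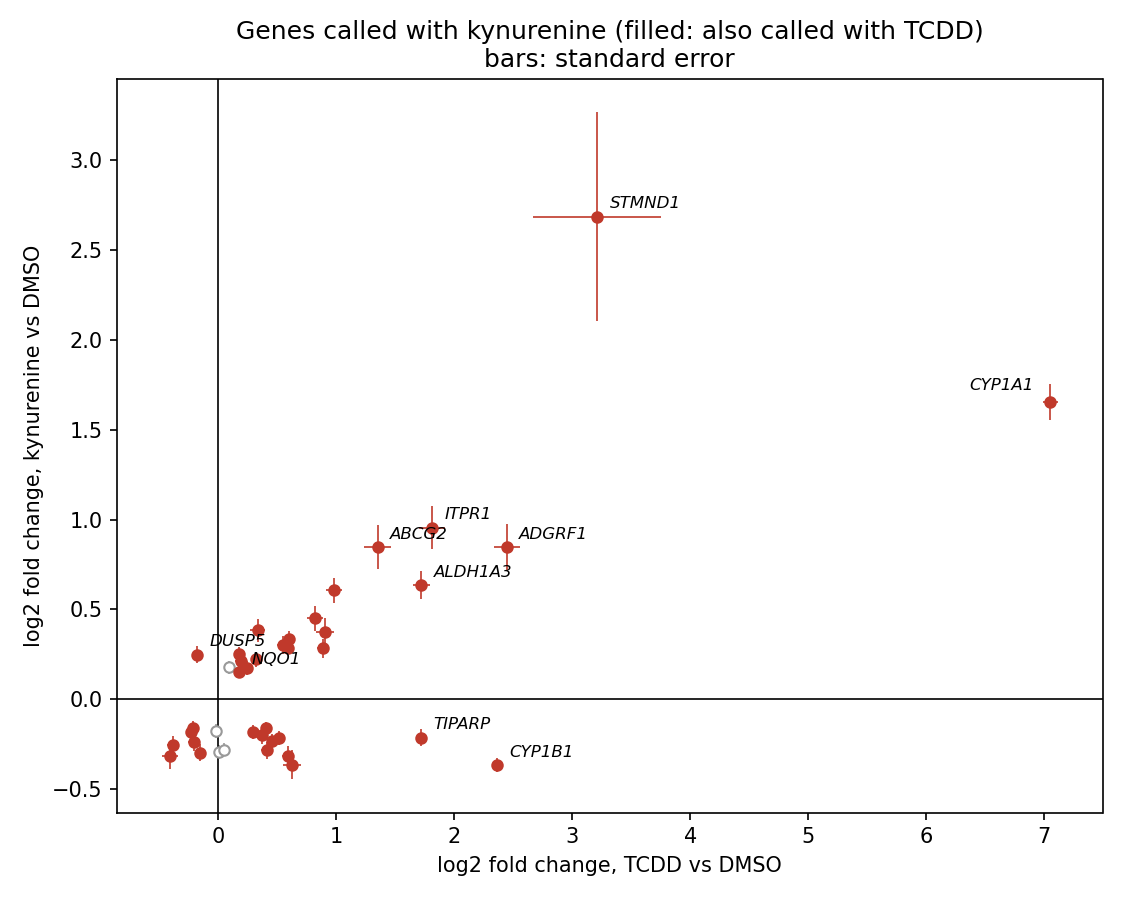
Log2 fold change with TCDD (horizontal axis) against that with kynurenine (vertical axis), both relative to DMSO, for the 40 genes called with kynurenine, with bars of 1 SE. Filled points mark the 36 genes also called with TCDD, and CYP1B1 lies at 2.36 with TCDD and -0.37 with kynurenine.

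CH223191 was compared with DMSO to measure what the antagonist does to AHR targets and to other genes. CYP1A1 fell from 3.22 ± 0.142 to 0.520 ± 0.188 CPM (SD, n = 3; log2 fold change -2.67 ± 0.205 SE, adjusted p = 9.0e-13), on 11, 12 and 16 reads in the 3 libraries. CYP1B1 fell from 126 ± 1.56 to 49.9 CPM (-1.33) and AHRR from 6.25 ± 0.354 to 2.44 ± 0.388 CPM (-1.34). Several of the large rises were in genes of the integrated stress response. ADM2, a peptide hormone of the adrenomedullin family, rose 7.93-fold from 1.59 ± 0.159 to 12.6 ± 0.973 CPM (log2 fold change 2.99 ± 0.125 SE, adjusted p = 1.9e-20), and DDIT4, an inhibitor of mTORC1, rose 5.25-fold from 51.5 ± 1.24 to 270 ± 10.8 CPM (2.39). NUPR1, a stress-induced chromatin protein (2.19), VLDLR, a lipoprotein receptor (2.06), CHAC1, a glutathione-degrading enzyme (1.94), and SESN2, an inhibitor of mTORC1 (1.57), rose as well.

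Of the list of ATF4 targets and integrated stress response genes, 21 of 24 rose and 2 fell (21 and 2 adjusted over the list alone), with a median log2 fold change of 1.04 (camera adjusted p = 1.3e-38, and 1.8e-04 with an estimated correlation). They included asparagine synthetase ASNS (1.41) and PSAT1 of serine synthesis (1.13). The 2 that fell were PPP1R15A (-0.26) and GDF15 (-0.10), and ATF5 did not pass (-0.09, adjusted p = 0.20), these 3 being named after their values were seen. The GDF15 call ended without DMSO replicate 1 or 3, TCDD replicate 1 or CH223191 replicate 2 or 3 (highest adjusted p = 0.18). Other large rises were in SLC6A9, a glycine transporter (2.22), SYTL5, a synaptotagmin-like protein (2.14), ULBP1, a ligand of the NKG2D receptor (1.98), TSC22D3, a glucocorticoid-induced leucine zipper protein (1.97), S100P, a calcium-binding protein (1.80), and MKX, a homeobox factor (1.64).

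Of the AHR targets 11 of 20 fell with CH223191 and 4 rose (12 and 4 adjusted over the list alone), with a median of -0.28 (adjusted p = 6.7e-05, and 0.0091 with an estimated correlation). EREG (-0.70), NEDD9 (-0.61) and TIPARP (-0.40) fell. NQO1 (0.29) and SLC7A5 (0.30) rose, and the remaining 2 that rose were RUNX2 (0.35) and CYP2S1 (0.15), named after their values were seen. The CYP2S1 call ended without DMSO replicate 1 or 2 or CH223191 replicate 1 or 2 (highest adjusted p = 0.12). ARNT rose (0.15, adjusted p = 0.019) but not without DMSO replicate 1 (0.13) or CH223191 replicate 1, nor with DESeq2 (0.053). AHR (-0.01, adjusted p = 0.85) and CYP1A2 (-0.13, 0.85) did not pass, and MYC (0.08, 0.099) passed under library totals alone (0.024), a filter of 5 CPM (0.042) and without CH223191 replicate 3 (0.029).

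Some lists of growth genes and that of the matrix response fell with CH223191. Of the ribosome biogenesis genes 18 of 30 fell and 0 rose (24 and 0 adjusted over the list alone), among them GRWD1 (-0.38) and URB2 (-0.42) (adjusted p = 1.0e-08, and 0.0062 with an estimated correlation). Of the G1/S and replication genes 20 of 25 fell and 0 rose (22 and 0 adjusted over the list alone), with the flap endonuclease FEN1 at -0.43 and the histone chaperone CHAF1A at -0.44 (adjusted p = 1.6e-14, and 0.0064 with an estimated correlation). Of the YAP and TGF-beta targets 12 of 25 fell and 5 rose (12 and 7 adjusted over the list alone; adjusted p = 0.0015, and 0.039 with an estimated correlation). EDN1, the endothelin precursor (-1.28), the matrix proteins CYR61 (-1.25), CTGF (-1.02) and THBS1 (-0.72) fell, and ID1 (0.47) rose. Of the G2/M genes 3 of 25 rose and 8 fell (3 and 9 adjusted over the list alone), and of the ribosomal proteins 2 of 82 rose and 3 fell (2 and 2 adjusted over the list alone). These lists were not called (adjusted p = 0.18 and 0.78, and 0.54 and 0.96 with an estimated correlation). ADGRF1 (-1.21), FGFBP1, a carrier of fibroblast growth factors (-1.15), SNHG9, a host RNA of small nucleolar RNAs (-1.12), EGR3, an immediate-early factor (-1.11), PCDH7, a protocadherin (-1.06), and CDIP1 (-0.99) were other large falls within the same limits. The CDIP1 call ended without CH223191 replicate 2 (-0.65, adjusted p = 0.068).

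The remaining 9 list calls with CH223191 did not hold with an estimated correlation. Of the immediate-early genes 20 of 39 fell and 6 rose (22 and 9 adjusted over the list alone), with FOSL1 at -0.62 and IER3 at -0.46 (adjusted p = 6.7e-05, and 0.18 with an estimated correlation). Of the NRF2 targets 10 of 22 rose and 1 fell (10 and 1 adjusted over the list alone), with the cystine transporter SLC7A11, also an ATF4 list member, at 1.52 and GCLC of glutathione synthesis at 0.29 (adjusted p = 2.3e-04, and 0.085 with an estimated correlation). Of the circadian and glucocorticoid-responsive genes 8 of 19 rose and 1 fell (8 and 2 adjusted over the list alone), such as TEF (0.42) and NR1D2 (0.30) (adjusted p = 0.0040, and 0.085 with an estimated correlation). Of the genes of tryptophan and kynurenine metabolism and transport 7 of 18 rose and 2 fell (7 and 2 adjusted over the list alone), with the glutamine transporter SLC1A5 at 0.49 and the tryptophanyl-tRNA synthetase WARS at 0.46 (adjusted p = 0.025, and 0.086 with an estimated correlation). Of the interferon-stimulated genes 9 of 20 rose and 0 fell (9 and 1 adjusted over the list alone), such as the RNA sensor DDX58 (0.44) and STAT2 (0.30) (adjusted p = 0.045, and 0.24 with an estimated correlation). Of the ZNF zinc finger genes 91 of 385 rose and 13 fell (86 and 13 adjusted over the list alone; adjusted p = 0.0018, and 0.21 with an estimated correlation). Of the heat shock genes 9 of 23 fell and 2 rose (9 and 2 adjusted over the list alone), with HSPA8 at -0.31 and HERPUD1 at 0.46 (adjusted p = 0.048, and 0.54 with an estimated correlation). Of the MYC targets 9 of 24 fell and 3 rose (9 and 3 adjusted over the list alone; adjusted p = 0.025, and 0.38 with an estimated correlation). Of the nucleotide synthesis genes 7 of 20 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 0.0049, and 0.24 with an estimated correlation). Among markers of other cell types, CSF1R rose (0.85), ESAM fell (-0.39) and TAGLN fell (-0.43), 1 of 9 immune, 1 of 8 endothelial and 1 of 8 fibroblast genes, and none of the 3 passed with DESeq2. The call ended for CSF1R without DMSO replicate 2 or 3 or CH223191 replicate 2 (highest adjusted p = 0.13), for ESAM without DMSO replicate 1 or 2 or CH223191 replicate 1 or 2 (0.13) and for TAGLN without DMSO replicate 1 or CH223191 replicate 3 (0.099).

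In total CH223191 changed 4470 of 13619 genes, 2171 higher and 2299 lower, with 342 at least 1.5-fold higher and 102 at least 1.5-fold lower. With library totals in place of composition factors the count was 4413, with 2599 higher and 1814 lower, so that the balance of rises and falls turned. With 1 library left out, list calls ended for heat shock genes (without DMSO replicate 3, TCDD replicate 1 or 3, kynurenine replicate 3 or CH223191 replicate 1 or 2, highest adjusted p = 0.15), interferon-stimulated genes (without DMSO replicate 1, kynurenine replicate 1 or CH223191 replicate 1 or 2, highest 0.086) and MYC targets (without CH223191 replicate 1, 0.060).

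**Figure D3:**
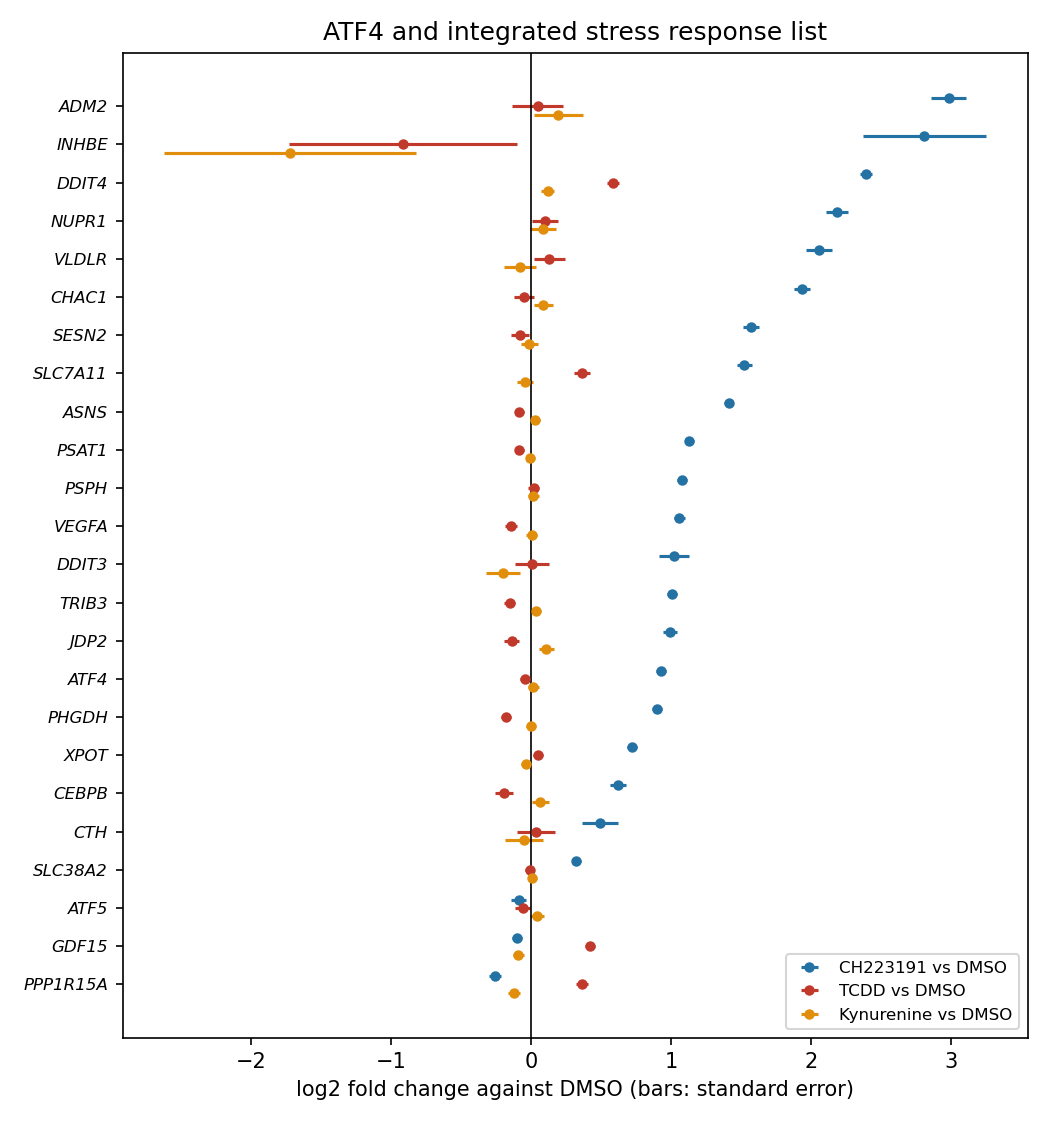
Log2 fold change relative to DMSO of the 24 measured genes of the ATF4 and integrated stress response list with TCDD, kynurenine and CH223191, with bars of 1 SE. With CH223191 21 genes were higher and 2 lower, with TCDD 4 were higher and 4 lower, and with kynurenine 0 passed the gene test.

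The compounds were also compared with each other. The labels state 10 µM and 1 h for each, but the protocol text does not mention CH223191, so whether its libraries were treated and prepared with the others is not known. The stated dose is high for TCDD and cannot be checked here, so the differences do not compare potency. Against kynurenine, TCDD gave higher CYP1A1 (log2 difference 5.40 ± 0.0535 SE, 42.2-fold), CYP1B1 (2.73), AHRR (2.18), TIPARP (1.93) and BMF (1.72), and lower OSR1 (-0.67), SOCS2 (-0.56) and CCL20, a chemokine (-0.56). LYPD3 (-0.83), LPP-AS2 (-0.73) and SLC35D3 (-0.57) were other large falls within the same limits. The call ended for LYPD3 without TCDD replicate 2 or 3 or kynurenine replicate 1 or 3 (highest adjusted p = 0.11), for LPP-AS2 without TCDD replicate 1 or 2 or kynurenine replicate 1 or 2 (0.17) and for SLC35D3 without TCDD replicate 1 or 3 or kynurenine replicate 2 or 3 (0.12). In this comparison 1252 genes differed, 695 higher with TCDD and 557 lower, and the count was 576 without TCDD replicate 3 and 658 without kynurenine replicate 1. Of the AHR targets 10 of 20 were higher with TCDD and 0 lower (13 and 1 adjusted over the list alone; adjusted p = 1.7e-22, and 1.1e-04 with an estimated correlation), the only list of 28 whose call held with an estimated correlation. Of the ribosomal proteins 28 of 82 were lower with TCDD (48 adjusted over the list alone; adjusted p = 3.7e-17, and 0.55 with an estimated correlation). NQO1 did not differ detectably, at 0.02 with a 95% confidence interval of -0.04 to 0.09.

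TCDD and CH223191 differed in 5052 genes, 2589 higher with TCDD and 2463 lower, and with library totals alone in 5040, 2199 higher and 2841 lower. CYP1A1 (9.72 ± 0.0838 SE, 842-fold), CYP1B1 (3.69), ADGRF1 (3.66), AHRR (3.24), CYP1A2 (2.74) and ALDH1A3 (2.51) were higher with TCDD, and ADM2 (-2.94), SLC6A9 (-2.41), ULBP1 (-2.09), NUPR1 (-2.09), CHAC1 (-1.99) and SYTL5 (-1.99) were lower. Of the 28 lists, the calls of AHR targets (14 of 20 higher, 4 lower; 0.00055) and ATF4 list genes (2 of 24 higher, 21 lower; 4.2e-04) held with an estimated correlation. The same counts were found adjusted over the list alone.

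Kynurenine and CH223191 differed in 4495 genes, 2267 higher with kynurenine and 2228 lower. With library totals alone the count was 4513, with 1765 higher and 2748 lower. CYP1A1 (4.32 ± 0.156 SE), ADGRF1 (2.06), CYP1A2 (1.47), FGFBP1 (1.43), ALDH1A3 (1.42) and ITPR1 (1.39) were higher with kynurenine, and ADM2 (-2.79), DDIT4 (-2.27), SYTL5 (-2.24), SLC6A9 (-2.18), VLDLR (-2.14) and ULBP1 (-2.12) were lower. CYP1B1 (0.97), AHRR (1.07) and TIPARP (0.18) were also higher with kynurenine than with CH223191. With an estimated correlation 5 of 28 lists kept their call, those of AHR targets, ATF4 genes, ribosome biogenesis, G1/S and replication, and YAP and TGF-beta targets.

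Genes called with both TCDD and kynurenine were mostly changed in the same direction. 19 genes were higher with both, where the numbers of calls alone would give 1.24, and 6 were lower with both against 1.11. 10 were higher with TCDD and lower with kynurenine against 1.12, and 1 was lower with TCDD and higher with kynurenine against 1.22. Of the 86 genes that TCDD raised at least 1.5-fold, kynurenine raised 12 and lowered 4, and CH223191 raised 8 and lowered 27. TCDD and CH223191 shared 325 genes lowered by both (134 given by the numbers of calls) and 144 raised by both (128), with 201 higher with TCDD and lower with CH223191 (136) and 96 the reverse (127). Kynurenine and CH223191 shared 3 genes higher with both (3.35), 16 lower with both (3.21), and 10 higher with kynurenine and lower with CH223191 (3.55). These expected numbers take the calls of each pair as independent, although the comparisons share their DMSO libraries, which can add to the genes that moved the same way. With shared controls and no effect, 100 simulations gave a mean of 0.13 genes higher and 0.07 lower with both TCDD and kynurenine, but such data hold few calls, so how much of the overlap comes from the controls is not settled.

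The comparisons against DMSO share its 3 libraries, which alone makes fold changes correlate across genes. Across 13619 genes, which are not independent replicates, Pearson's r was 0.457 for TCDD and kynurenine, against a mean of 0.485 in 100 simulations with no effect. It was 0.137 for TCDD and CH223191 against 0.483, but -0.0029 with a filter of 5 CPM and 0.208, 0.254 and 0.204 without DMSO replicate 1, 2 and 3, so it rests on these choices. It was 0.273 for kynurenine and CH223191 against 0.495. A compound's own effects widen its fold changes, and the simulations lack them. An r below the simulated mean therefore does not show less agreement than the shared controls give. The covariance less that of the simulations was 0.00821, -0.000724 and 0.00434 for these 3 pairs. The controls were not split between the comparisons here, so part of the excess for TCDD with kynurenine and for kynurenine with CH223191 can come from the controls.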

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

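The tests of scaling and of single libraries in this part were chosen only after the result was seen. 11 genes were called in opposite directions with TCDD and with kynurenine and also differed between the compounds by edgeR, a condition for listing them. Opposite calls against the same DMSO libraries make that difference nearly certain. The p-values of the differences below are therefore no separate evidence, and the differences show size only.

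CYP1B1 rose with TCDD (log2 fold change 2.36) and fell with kynurenine (-0.37), a difference of 2.73 (adjusted p = 1.1e-35). The same held for the AHR feedback enzyme TIPARP (1.72 and -0.21, difference 1.93, adjusted p = 9.6e-29), MB21D2 (0.63 and -0.36, difference 0.99, 7.4e-12), the kinase PIM1 (0.59 and -0.32, difference 0.91, 2.0e-15), the hyaluronan-degrading CEMIP (0.51 and -0.22, difference 0.73, 3.9e-16), the scaffold NEDD9 (0.41 and -0.28, difference 0.69, 5.1e-14) and the EGF receptor ligand EREG (0.45 and -0.23, difference 0.68, 2.7e-15). It also held for PPFIBP2 (0.37 and -0.20, difference 0.57, 5.3e-12), CLDND1 (0.41 and -0.16, difference 0.57, 3.5e-14) and LGR5, an intestinal stem cell receptor (0.29 and -0.18, difference 0.48, 1.8e-11). DUSP5, a phosphatase of ERK, went the other way (-0.18 and 0.25, difference -0.43, 6.6e-08), and its kynurenine call ended without DMSO replicate 2 (0.21, adjusted p = 0.085). PPFIBP2, CLDND1 and DUSP5 were chosen after their values were seen. CH223191 lowered CYP1B1 (-1.33), CLDND1 (-0.72), EREG (-0.70), MB21D2 (-0.66), NEDD9 (-0.61), PIM1 (-0.53), TIPARP (-0.40), CEMIP (-0.19), LGR5 (-0.18) and DUSP5 (-0.15), and PPFIBP2 did not pass (-0.10, adjusted p = 0.093).

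For the 10 genes that TCDD raised and kynurenine lowered, the value closest to 0 over the 10 genes and 3 scalings was -0.16. The scalings hardly differed here, as the 40 calls with TMM were shared by RLE factors and by library totals, so this test leaves the scaling of the libraries open. A single aberrant library is argued against for CYP1B1, CEMIP, EREG, NEDD9 and PIM1. Their calls held with each of the 6 libraries compared left out (highest adjusted p = 0.040, in CEMIP). For the other genes it stays open. All 10 genes stayed below 0 in these fits, with -0.14 in CLDND1 closest to 0, but they were chosen for their fall. Calls of the other genes ended in part, also at similar fold changes, as in MB21D2 (-0.40 to -0.33). Kynurenine replicate 1 stood apart from its group. Of the 10 genes 7, 5 and 6 passed without DMSO replicate 1, 2 and 3, and 5, 6 and 8 without kynurenine replicate 1, 2 and 3. Of 6 such fits CYP1B1, CEMIP, EREG, NEDD9 and PIM1 passed in 6, LGR5 in 3, CLDND1 in 2, PPFIBP2 in 1, TIPARP in 1 and MB21D2 in 0. LGR5 lost its call without DMSO replicate 2 or kynurenine replicate 1 or 3 (highest adjusted p = 0.19), CLDND1 without DMSO replicate 2 or 3, TCDD replicate 1 or 2, kynurenine replicate 1 or 2 or CH223191 replicate 2 (0.29), and PPFIBP2 without any DMSO library, TCDD replicate 1, kynurenine replicate 1 or 2 or CH223191 replicate 2 (0.19). Whether kynurenine lowers part of the AHR-dependent expression present in DMSO stays open as well, and the design holds no dose or time series to test it.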

How the results depend on the processing

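Removal of GC and length trends was chosen after seeing the data, and the other alternatives were planned. Over all settings, 13946 values of named genes kept direction and side of the threshold, 459 lost their call, 88 gained one and 24 changed direction. Of the list tests 1144 kept both, 132 lost the call and 2 changed direction, and of the counts of genes and lists 238 stayed within 1.5 times and 21 did not. DESeq2 gave 1295, 40 and 3637 genes with TCDD, kynurenine and CH223191 against DMSO, 35 of the 40 shared, and the replicate block gave 1537, 38 and 4366. For each change below the cause was not tested.

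With an estimated correlation, 1, 0, 5, 1, 2 and 5 lists were called for TCDD, kynurenine and CH223191 against DMSO, TCDD against kynurenine, TCDD against CH223191 and kynurenine against CH223191. Fry called 8 lists with TCDD, 0 with kynurenine and 17 with CH223191 against DMSO, where camera with the preset correlation called 12, 4 and 14. Between compounds fry called 5 for TCDD against kynurenine, 20 for TCDD against CH223191 and 19 for kynurenine against CH223191. Kynurenine changed 65 genes with no low-count filter and 26 with only the 2 groups compared, TCDD against kynurenine had 10 lists with no filter, and TCDD changed 1055 genes with GC and length trends removed.

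With 1 library left out, TCDD changed 805 (without TCDD replicate 3) to 1912 genes, TCDD against kynurenine 576 (without TCDD replicate 3) to 1323, and lists called ranged from 3 (without DMSO replicate 1) to 9 (without kynurenine replicate 1) with kynurenine and from 4 (without TCDD replicate 2) to 11 (without TCDD replicate 1) for TCDD against kynurenine. The Cytoplasmic ribosomal proteins list test, Kynurenine vs DMSO, ran from 9.3e-13 (without DMSO replicate 1) to 0.38 (without DMSO replicate 2).

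Apart from RNA18S5, the genes below that changed direction had no call with 12 libraries. RNA18S5, not among the named genes counted above, was called with TCDD in both directions, at -2.84 and, without DMSO replicate 1, at 3.02. AHR with CH223191 was 0.013 under library totals and 0.0014 at 5 CPM. For kynurenine against CH223191, AHR was 0.00097 with no filter, 0.0011 with DESeq2, 0.00023 with the 2 groups only and 0.012 with trends removed. EGFL7 with TCDD was 0.055 with trends removed. The correlation of TCDD and CH223191 was -0.0029 at 5 CPM. With 1 library left out, ARNT ran from -0.053 to 0.0073 with TCDD and -0.015 to 0.045 with kynurenine. AHR ran from -0.049 to 0.015 with kynurenine, -0.038 to 0.017 with CH223191 and -0.037 to 0.022 for kynurenine against CH223191. FLT1 ran from -0.13 to 0.025 with TCDD, EGFL7 from -0.098 to 0.013 with kynurenine, CYP1A2 from -0.58 to 0.29 and CD74 from -0.095 to 0.86 with CH223191, and LYZ from -0.063 to 1.06 for TCDD against kynurenine.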

Other observations

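The tests of the ATF4, EDC3 and baseline explanations in this part were chosen only after the result was seen, and the counts over other splits of the libraries were planned. CDX2, an intestinal transcription factor, rose with TCDD (log2 fold change 0.41) and fell with CH223191 (-0.37). Its list of colon epithelial differentiation markers had 1 of 14 higher and 2 lower with TCDD (1 and 5 adjusted over the list alone; camera adjusted p = 0.51). PROX1, a homeobox factor, rose with TCDD (0.65) and with CH223191 (0.57). Its list of Wnt and beta-catenin targets had 3 of 22 higher and 4 lower with TCDD (4 and 6 adjusted over the list alone; camera adjusted p = 0.96). With TCDD, DDIT4 (0.58), GDF15 (0.42), SLC7A11 (0.37) and PPP1R15A (0.37) rose although the ATF4 list as a whole had 4 genes higher and 4 lower of 24 (camera adjusted p = 0.86), and IER3, an immediate-early gene, rose (0.38) although that list had 3 higher and 5 lower of 39 (3 and 6 adjusted over the list alone; adjusted p = 0.60). CDX2, PROX1, IER3 and GDF15 were singled out after their values were seen.

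CH223191 raised most ATF4-list genes. The list median log2 fold change was 1.04 with TMM and RLE factors and 1.07 with library totals. The median of all genes was 0.00097 with TMM and 0.0256 with library totals, which kept 3985 of 4470 calls. These scalings differed too little to remove a rise of this size, so exchanging them does not decide by itself. A scaling factor, however, moves all genes of a library alike. With TMM the list median was 1.04 where the median of all genes was 0.00097, and 21 of 24 members rose. This argues against scaling as the cause of the list's rise relative to all genes, which is all that these values show. A GC content or transcript length trend is argued against as the whole cause, since with both removed the median was 1.04, with 21 genes higher and 1 lower of 24. TCDD did not lower the list as a mirror image would, with a median of -0.027 (SE over members 0.0574), above the bound of -0.26. The bound was set after the data were seen, and the members are not independent replicates. The bound also assumes that blocking AHR mirrors its activation, which was not tested here. NQO1 and SLC7A5 of the AHR target list rose with both TCDD and CH223191. Whether their rise with CH223191 came through AHR is not known, and NQO1 is also on the NRF2 list. Dependence of the ATF4 list's rise on AHR therefore stays open. An action of CH223191 on the integrated stress response apart from AHR may explain the rise. These libraries cannot separate this hypothesis from dependence on AHR or from other effects of 10 µM of the compound.

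EDC3, an mRNA decapping factor that lies 23250 bp from CYP1A1 on chromosome 15, rose with TCDD (0.84, adjusted p = 2.9e-19) and fell with CH223191 (-0.30, adjusted p = 1.9e-07). It was chosen after its values were seen, as were the neighbours CLK3 (0.29 and -0.48), CSK (0.29 and -0.10) and, beside AHRR, EXOC3 (0.29 and -0.18). CLK3 overlaps EDC3 on the opposite strand, and with the strand setting of the counting not stated, CLK3 and EDC3 may share reads. The CSK call with CH223191 (adjusted p = 0.049) ended in 9 of 12 fits with a library left out, all but those without DMSO replicate 3, kynurenine replicate 1 and CH223191 replicate 1 (highest 0.25). Beside AHRR, EXOC3-AS1 (0.10, adjusted p = 0.75), PDCD6 (0.02, 0.86), PP7080 (0.13, 0.30), SDHA (-0.04, 0.55) and SLC9A3 (0.54, 0.11) did not pass with TCDD. Of these PDCD6 fell with CH223191 (-0.17, adjusted p = 0.0045), about as much as EXOC3, and the other 4 did not pass, with EXOC3-AS1 at -0.09 (0.69), PP7080 at 0.06 (0.61), SDHA at -0.08 (0.071) and SLC9A3 at -0.32 (0.33). For the fall, read-through from CYP1A1 is argued against, because EDC3 fell by 14.36 ± 1.19 CPM and CYP1A1 fell by 2.695 ± 0.236 CPM (SD), a difference of 11.66 CPM. For the rise, 60.9 ± 2.75 CPM against 424 ± 15.9 CPM for CYP1A1 (a difference of -363.5 CPM), read-through and regulation of EDC3 cannot be told apart, because no values per exon were analysed here. CYP1B1-AS1 (1.91) and RMDN2 (0.43), which overlap CYP1B1 on the other strand, rose with TCDD and may hold reads of CYP1B1. The RMDN2 call ended without DMSO replicate 1 (adjusted p = 0.056).

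Genes with high AHR-dependent expression already in DMSO might be those that kynurenine lowered. Over the 86 genes that TCDD raised at least 1.5-fold, the kynurenine effect was correlated with the position of DMSO between CH223191 and TCDD, with the DMSO libraries split between both measures. Spearman's rank correlation was -0.165, -0.113 and -0.138 in 3 splits (permutation p = 0.131, 0.299 and 0.204, 100000 permutations), and Pearson's r -0.0258, -0.00588 and 0.0203. The median, -0.138, leaves this open.

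Other splits of the libraries were counted with fits of the 2 groups compared. TCDD against DMSO gave 1657 genes and at most 0 by edgeR in another split, kynurenine 26 and at most 2, CH223191 4588 and at most 0, TCDD against kynurenine 1224 and at most 0, TCDD against CH223191 5339 and at most 0, and kynurenine against CH223191 4493 and at most 0. In each, 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. For the test among 4 groups, 1 of 100 splits, the real one, gave as many as 5932 genes, with 2713 the highest other. A chance split of these libraries is thus excluded at 0.05. A difference between cultures or batches is not, since it is not known whether the libraries of a group were separate cultures.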
